A study of Arabidopsis thaliana with 54 samples.

How the data were processed

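Small RNA was sequenced from whole Arabidopsis thaliana Col-0 seedlings (shoot, hypocotyl and root). After 48 h of stratification the seedlings spent 10 days in 12 h light and 12 h dark. On day 11 they went to long day (16 h light), stayed in the starting photoperiod (equinox day, 12 h light) or went to short day (8 h light), and they were collected on day 13. Each photoperiod was sampled at Zeitgeber times (hours after lights on) ZT 4, 8, 12, 16, 20 and 24, with 3 replicates per time, named A, B and C. This gave 54 libraries in 18 groups of 3, 18 libraries per photoperiod. Per the labels, RNA of integrity number 7 or more was taken from about 200 mg of tissue, and small RNA of up to 40 nucleotides was kept by gel. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these samples.

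The deposited table holds read counts per library, and its values were whole numbers in every column. The submitters' processing notes name cutadapt 3.4, Bowtie2 2.5.1 and SAMtools. The settings of these tools, the genome build, the counting rule and the handling of reads that match several places are not given in the sources used here. The table has 286 mature microRNA features, 223365 features with a numbered trex name, and 1 entry named genome. Of the microRNA features, 40 join several names that share 1 mature sequence. What the trex names stand for is not given in the sources used here, so these features are reported as counts, with at most 2 named per direction. The genome entry held 86.1% of all counts and was left out of library totals and tests, which rest on the 223651 other features.

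Counts were fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with 1 coefficient for each of the 18 groups. Scaling used TMM factors, and the filterByExpr filter used a minimum count of 10 and a minimum total of 15. The filter left 8869 features, 149 of them microRNAs and 8720 trex features, which held 98.1% of the counts outside the genome entry. The other 137 microRNA features were too rare to test. Each contrast was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over the 8869 features, with a threshold of 0.05. Of the 13 contrasts, 3 compared photoperiods as means over the 6 times, 3 tested all times of 1 photoperiod jointly, 1 tested the interaction of photoperiod and time, and 6 compared long day with short day at a single time. The fit had 36 residual degrees of freedom, a prior of 12.5, a common dispersion of 0.208 and a typical biological coefficient of variation of 0.456. Levels are CPM from edgeR's cpm function on TMM-scaled totals without the genome entry. Log2 fold changes carry the standard error that the test statistic implies.

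Features of microRNAs were grouped in 12 lists fixed before the data were examined, as were the contrasts, the first set of alternative settings and the rule for named genes. Another 13 lists could not be used, since no feature of the table carries a name from them. Among them were loci of trans-acting siRNAs, phasiRNA-producing genes, clock genes, small RNA pathway genes, photosynthesis genes and root markers. The others were plastid, mitochondrial, tRNA, rRNA, snoRNA, snRNA and transposable element features. Whether trex features include such RNAs is not known. For each list the members past the threshold were counted, also adjusted over the list alone. The 10 lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the lists of a contrast. In the time tests, lists were compared with all other features by a two-sided Fisher's exact test. Shares of counts were compared by two-sided permutation tests with 100000 draws, the labels permuted within each time.

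Genes were named by this rule. From each list came up to 4 members past the threshold with the largest absolute log2 fold change, or the smallest p in the time tests, and where none passed up to 2 with the highest mean CPM, given as values; for the time tests such lists are given as counts. Further names were the 6 higher and 6 lower features with the largest changes per photoperiod contrast (mean CPM of at least 10 and the same sign at 5 or more of 6 times), the 8 smallest p per time test, the 2 smallest p per single time and the 10 highest mean CPM. These last parts picked mostly trex features, which have no gene name. Any microRNA named outside the rule is said to be so, except those given for abundance, exon position, the end of light or arm ratios. MicroRNA genes and their neighbours were taken by exact name from the RefSeq annotation of TAIR10.1, where all 193 mature names of the tested features were found; coordinates are not printed, because the build behind the counts is unknown.

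The alternatives were DESeq2 size factors, no TMM factors, the 10 most abundant features left out, no filter, another filter (1 CPM in 27 libraries, which left 10324 features), DESeq2 1.42.0 in place of edgeR, replicate letters as a block, only the libraries compared, a cosine with a period of 24 h for time, hours of light as a number, microRNA families summed, a threshold of 0.01, an absolute log2 change of at least 1, and each library and each replicate letter left out. Added after the data were seen were the share of the genome entry as a covariate, totals with the genome entry and no TMM, microRNAs fitted alone for the counts, a pair of left-out sets of libraries, and each library left out for the single times. For the lists, families summed, the replicate block and microRNAs fitted alone were fixed beforehand for the photoperiods, and the list tests in all other fits were added after the data were seen. The libraries held 13.7 to 23.3 M counts in total and 1.33 to 3.59 M outside the genome entry. Reads were amplified without molecular identifiers, so counting precision covers counting error only. The method was tested on 8869 simulated features with this design. For long day against short day it found 4, 29, 50 and 49 of 50 features changed 1.5-, 2-, 4- and 8-fold, with 4.26% false calls. For time in equinox day it found 0, 0, 17 and 31 of 50, with 2.04% false calls. For the single time ZT 16 it found 0, 1, 18 and 35 of 50, with 8.53% false calls (11 of 129), above the threshold of 5%. Simulated features were drawn independently of each other, so these false-call shares do not cover structure shared by features of real libraries.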

Results

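Small RNA counts were collected from 54 libraries of whole Arabidopsis seedlings, with 3 libraries for each of 6 times in long day, equinox day and short day. Libraries held 13.7 to 23.3 M counts (median 17.6 M), of which the single genome entry took 79.6% to 92.9%. The counts outside that entry came to 1.33 to 3.59 M per library (median 2.32 M), and microRNA counts to 114873 to 409911. Between 176 and 220 microRNA features were detected in a library. Values in CPM are means ± SD over libraries (n = 18 per photoperiod, n = 3 per time), log2 fold changes carry their SE, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

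The most abundant microRNA was miR161.1, which targets pentatricopeptide repeat transcripts, with 32772 ± 10291 CPM (n = 54) and 31.2% of microRNA counts. It was followed by miR158a-3p with 13918 ± 3573 CPM, by miR162-3p, which targets DCL1, with 8822 ± 3041 CPM, and by miR156a-f-5p, which restrains SPL factors of the adult phase, with 5815 ± 2105 CPM. The feature for miR166-3p, which targets HD-ZIP III transcripts, held 5446 ± 1668 CPM and miR5026 held 4792 ± 1718 CPM. MicroRNAs made up 10.1% of the counts outside the genome entry, and the trex feature trex5742 alone made up 25.0%. The first principal component of log2 CPM took 21.7% of the variance and the second 14.1%. Of the short-day libraries, 5 lay beyond every long-day and equinox-day library on the first component: ZT 24 C, ZT 4 B, ZT 12 C, ZT 16 B and ZT 20 A. How reads of near-identical microRNAs were assigned is not given, so values within the families miR156 with miR157, miR165 with miR166, miR172 and miR398 are uncertain between members.

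Long day against short day set the widest difference in day length, and compared means over the same Zeitgeber times. More of these times fell in light under long day, so a feature that only follows light can pass here too. The same holds for the contrasts with equinox day. Under long day, miR169f-3p, from the family that targets NF-YA transcripts, stood at 124 ± 39.7 CPM against 54.8 ± 24.2 under short day, a log2 fold change of 1.18 ± 0.16. Throughout, targets are named by family, and whether the counted arm acts on them was not tested. The copper microRNA miR398b/c-3p, which targets superoxide dismutase transcripts, was also higher under long day, at 4005 ± 1290.2 against 2571 ± 1557 CPM. The juvenile-phase microRNA miR156a-f-5p was lower under long day, at 4598 ± 1473 against 6779 ± 2043 CPM (log2 fold change -0.56 ± 0.15). So was miR173-5p, which starts trans-acting siRNA production from TAS1 and TAS2, at 96.0 ± 33.8 against 180.0 ± 80.7 CPM. Of 149 microRNAs tested, 43 passed, 12 higher and 31 lower under long day (47 when adjusted over the microRNAs alone). The median log2 fold change of all microRNAs was -0.17.

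In the miR156 and miR157 list, 4 of 12 members were lower under long day and 0 higher (6 and 0 adjusted over the list alone). They were miR156f-3p (log2 fold change -0.76 ± 0.26, adjusted p = 0.0279, lower at 5 of 6 times) and miR156b-3p (-0.57 ± 0.17, adjusted p = 0.0132, 6 of 6 times). The others were miR156a-f-5p (adjusted p = 0.00578, 6 of 6 times) and miR156c-3p (-0.38 ± 0.14, adjusted p = 0.0400). Camera called the list lower, with a median log2 fold change of -0.36 and adjusted p = 0.0499988, just under the threshold, and gave adjusted p = 0.812 with an estimated correlation. Fry gave adjusted p = 0.133. This camera call was lost with totals that include the genome entry (adjusted p = 0.135), with microRNAs fitted alone (0.238), with the replicate letters as a block (0.0513) and without the libraries of letter A (0.226) or C (0.124). Of the miR172 list, which acts on AP2-like repressors of flowering, 0 of 3 members passed (edgeR; 0 higher and 2 lower adjusted over the list alone). There miR172a/b-3p stood at 7.13 ± 4.70 against 10.6 ± 5.06 CPM (adjusted p = 0.0868), and the log2 fold change of miR172b/e-5p was -0.05 ± 0.25 (adjusted p = 0.911).

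Of the auxin response microRNAs, 1 of 14 was higher and 6 lower under long day, with the same numbers adjusted over the list alone. The miR167a-5p/b feature, which targets ARF6 and ARF8, stood at 382 ± 128 against 658 ± 298 CPM (log2 fold change -0.74 ± 0.20, adjusted p = 0.00553, lower at 5 of 6 times). Its relative miR167c-5p fell by 0.65 on the log2 scale (adjusted p = 0.0103). The arms of miR390b, which directs tasiRNAs against ARF transcripts, moved apart: miR390b-3p rose by 0.81 ± 0.18 on the log2 scale (37.1 ± 10.1 against 22.3 ± 11.2 CPM, adjusted p = 0.000864, 6 of 6 times). The 5p feature, which pools MIR390a and MIR390b, fell by 0.61 ± 0.17 (83.7 ± 18.4 against 130.4 ± 44.6 CPM, adjusted p = 0.00596, 6 of 6 times). Of the tasiRNA and phasiRNA triggers, 1 of 12 was higher and 6 lower (1 and 7 adjusted over the list alone). The lower ones included miR400, in an intron of AT1G32583 (-0.90 ± 0.34, adjusted p = 0.0420), and miR173-5p (-0.86 ± 0.20, adjusted p = 0.00170, 6 of 6 times). Camera gave adjusted p = 0.0822 for the auxin and the trigger lists, and with the preset correlation called each lower in 7 of 13 other fits (adjusted p from 0.000486 to 0.529). With an estimated correlation camera gave adjusted p = 0.812 for both lists.

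Of the miR169 to miR171 list, 1 of 7 was higher and 3 lower, also adjusted over the list alone. Beside miR169f-3p (adjusted p = 2.27e-07, 6 of 6 times), the lower members were miR170-3p (-1.24 ± 0.34, adjusted p = 0.00670), miR171a-3p (-0.77 ± 0.19, adjusted p = 0.00288, 20.6 ± 7.96 against 35.5 ± 15.2 CPM), which targets HAM transcripts, and miR171b-5p (-0.64 ± 0.20, adjusted p = 0.0147). Of the meristem and organ patterning microRNAs, 1 of 14 was higher and 2 lower, also adjusted over the list alone. The higher one was miR165a-5p at 374 ± 146 against 266 ± 116 CPM (0.47 ± 0.13, adjusted p = 0.00893). The lower ones were miR394, which targets an F-box transcript (-0.69 ± 0.20, adjusted p = 0.0104) and miR396a-5p, which targets GRF transcripts (-0.68 ± 0.21, adjusted p = 0.0139). Of the miR159 and miR319 list, 1 of 6 was higher and 0 lower, also adjusted over the list alone. That member was miR159b-5p at 17.5 ± 9.15 against 8.81 ± 4.54 CPM (0.95 ± 0.20, adjusted p = 0.000626, 5 of 6 times). The median of that list was -0.07 and its mean 0.02 with an upward camera direction, and its median turned to 0.02 with totals that include the genome entry and to 0.10 with microRNAs alone.

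The members of the nutrient lists that passed were higher under long day. Of the copper microRNAs, 2 of 6 were higher and 0 lower, also adjusted over the list alone. They were miR398a-3p (0.73 ± 0.18, 68.1 ± 22.1 against 41.3 ± 20.4 CPM, adjusted p = 0.00289) and miR398b/c-3p (0.71 ± 0.20, adjusted p = 0.00800), each at 5 of 6 times. Both features of the sulfate microRNA miR395, which targets ATP sulfurylase transcripts, were higher, also adjusted over the list alone. They were miR395b/c/f at 126 ± 37.8 against 82.1 ± 35.1 CPM (0.64 ± 0.17, adjusted p = 0.00578) and miR395a/d/e at 56.5 ± 15.3 against 38.7 ± 16.7 CPM (0.55 ± 0.18, adjusted p = 0.0244), each at 6 of 6 times. Of the phosphate list, 1 of 2 was higher and 0 lower, also adjusted over the list alone. It was miR399b/c-3p, which targets PHO2, at 25.9 ± 10.2 against 18.02 ± 4.82 CPM (0.49 ± 0.16, adjusted p = 0.0230, 6 of 6 times). Of the small RNA pathway feedback list, 0 of 7 passed, also adjusted over the list alone. There miR162-3p had a log2 fold change of 0.15 ± 0.15 (adjusted p = 0.497) and miR403-3p, which targets AGO2, of -0.14 ± 0.13 (adjusted p = 0.464). Of the list of young microRNAs, which is a selection and leaves out families such as miR779, miR829, miR831 and miR852, 0 of 34 were higher and 6 lower (0 and 3 adjusted over the list alone). Among the lower ones were miR841a-3p (-1.18 ± 0.24, adjusted p = 0.000382, 6 of 6 times), miR822-5p at 78.3 ± 22.6 against 137 ± 61.2 CPM (-0.76 ± 0.19, adjusted p = 0.00272, 6 of 6 times), miR840-5p (-0.60 ± 0.22, adjusted p = 0.0416) and miR823 (-0.55 ± 0.19, adjusted p = 0.0301). Fry found that members of the young list changed in either direction (adjusted p = 0.0275), while camera gave adjusted p = 0.0822 for this list and 0.0831 for the copper list. In the 13 other fits, with the preset correlation, camera called the young list lower in 7 (adjusted p from 9.95e-05 to 0.529) and the copper list higher in 1 (0.0425 to 0.463). With an estimated correlation camera gave adjusted p = 0.812 for the young and the copper list.

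Outside the lists, and named after their values were seen, miR5634 fell furthest of the microRNAs, from 6.09 ± 3.15 CPM under short day to 1.46 ± 1.09 under long day (-2.11 ± 0.28, adjusted p = 2.36e-07, 6 of 6 times). By the same test miR391-3p fell from 46.2 ± 14.95 to 23.7 ± 6.16 CPM (-0.96 ± 0.17, adjusted p = 4.25e-05, 6 of 6 times) and miR852 by 1.07 ± 0.24 on the log2 scale (adjusted p = 0.00111). Higher under long day were miR831-3p (0.90 ± 0.24, adjusted p = 0.00532, 5 of 6 times) and miR779.2 (0.43 ± 0.16, adjusted p = 0.0447, 3 of 6 times, lost in 30 of the 54 fits without 1 library). The annotation places miR840-5p in an exon of AT2G02750, miR5654-3p in an exon of AT1G32583, miR5642b in an exon of AT2G01008 and miR5595a in an exon of AT2G23550. It also places miR472-5p, which passed here, in an exon of AT1G12290. Another is miR3932b-5p, which passed between short day and equinox day, in an exon of AT4G13575. The counts of the features of these microRNAs cannot be told from fragments of those transcripts. The annotation places miR852 inside AT4G14500 but in no exon, and miR5634 opposite to AT4G30750. Over all features, 2229 of 8869 passed, 955 higher and 1274 lower. The trex features with the largest changes under the naming rule were trex763666 (log2 fold change 4.34 ± 0.41, adjusted p = 9.58e-11) and trex256809 (2.40 ± 0.27, adjusted p = 4.60e-09), both higher. Both lower, with adjusted p = 3.20e-11, were trex846212 (-3.12 ± 0.28) and trex1472916 (-3.11 ± 0.28, 50.8 ± 33.9 against 432 ± 240.3 CPM). With totals that include the genome entry, 1132 features were higher and 929 lower, and 12 microRNAs higher and 16 lower, while DESeq2 called 852 features higher and 1750 lower. With microRNAs fitted alone 33 were higher and 34 lower. With the 5 short-day libraries that lay apart left out, 994 features and 41 microRNAs passed, and 33 of the 43 microRNAs were kept. Without any 1 of the 54 libraries, 29 of the 43 still passed. Of those named above, miR156f-3p was lost without short day ZT 8 C or ZT 16 C, and miR395a/d/e in 5 fits, miR399b/c-3p in 8, miR156c-3p in 14, miR400 in 15 and miR840-5p in 17, and miR823 without short day ZT 24 B or ZT 20 A.

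**Figure D1:**
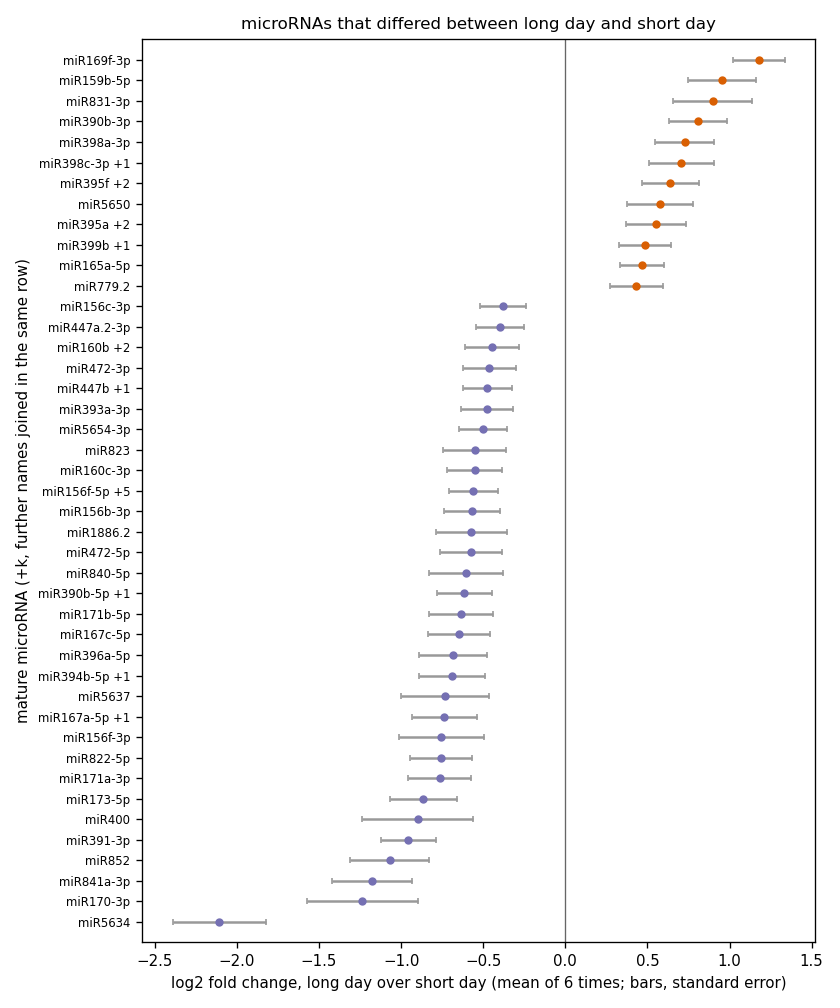
Log2 fold change of long day over short day (± SE, 18 libraries per photoperiod) for the 43 microRNA features past an adjusted p of 0.05 in edgeR's quasi-likelihood test. Points right of 0 are higher under long day (12 features, up to miR169f-3p at 1.18), points left of 0 lower (31 features, down to miR5634 at -2.11); with totals that include the genome entry the counts were 12 and 16.

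Long day against equinox day set 4 more hours of light against the photoperiod of germination. Only the long-day seedlings had changed photoperiod, on day 11, so day length and the change itself cannot be told apart here. Under long day, miR398a-3p was higher at 68.1 ± 22.1 against 43.6 ± 17.4 CPM, and miR159b-5p at 17.5 ± 9.15 against 10.4 ± 5.88 CPM. The abundant miR166-3p feature was lower, at 4555 ± 1214 against 6299 ± 1398 CPM, together with miR165a-3p/b, which acts on the same HD-ZIP III transcripts, at 1242 ± 228 against 1629 ± 425 CPM. Of 149 microRNAs, 11 passed edgeR's quasi-likelihood test, 3 higher and 8 lower (4 adjusted over the microRNAs alone), and the median log2 fold change of all microRNAs was -0.16.

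Of the meristem list, 0 of 14 were higher and 2 lower, also adjusted over the list alone. They were miR166-3p (log2 fold change -0.47 ± 0.13, adjusted p = 0.00615) and miR165a-3p/b (-0.39 ± 0.13, adjusted p = 0.0406), each at 6 of 6 times. The list median of -0.10 turned to 0.06 with totals that include the genome entry and to 0.04 with microRNAs alone. Of the copper list, 1 of 6 was higher, also adjusted over the list alone. It was miR398a-3p (0.65 ± 0.18, adjusted p = 0.00909, 6 of 6 times). Of the miR159 and miR319 list, 1 of 6 was higher and 0 lower (1 and 1 adjusted over the list alone). It was miR159b-5p (0.76 ± 0.20, adjusted p = 0.00614, 5 of 6 times). Of the miR156 and miR157 list, 0 of 12 were higher and 1 lower (0 adjusted over the list alone), which was miR156j at 4.05 ± 2.59 against 6.63 ± 3.47 CPM (-0.70 ± 0.23, adjusted p = 0.0327, 6 of 6 times). Of the auxin list, 0 of 14 were higher and 1 lower (0 adjusted over the list alone), which was miR167c-3p at 310.2 ± 94.7 against 427 ± 144 CPM (-0.46 ± 0.15, adjusted p = 0.0317, 6 of 6 times). Of the young list, 1 of 34 was higher and 1 lower (0 adjusted over the list alone). They were miR858a, which targets MYB transcripts of flavonoid synthesis, at 12.7 ± 3.95 against 8.93 ± 3.50 CPM (0.51 ± 0.17, adjusted p = 0.0323), and miR841a-3p (-0.72 ± 0.25, adjusted p = 0.0411).

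In the remaining lists no member passed edgeR's test, and none did adjusted over the list alone. The values there were miR172a/b-3p (log2 fold change 0.23 ± 0.32, adjusted p = 0.692), miR172b/e-5p (0.36 ± 0.25, adjusted p = 0.371), miR162-3p (-0.22), miR403-3p (-0.28 ± 0.13, adjusted p = 0.144), miR827 (-0.10) and the trigger miR161.1 (-0.17). Without passing, the medians of the miR169 to miR171 (-0.11), feedback (-0.12), phosphate (-0.16) and trigger (-0.16) lists turned positive with totals that include the genome entry (0.05, 0.04, 0.01 and 0.01), and that of miR169 to miR171 also with microRNAs alone (0.06). Camera gave adjusted p = 0.4499 or more for every list. With the preset correlation it called the miR156 and miR157 list (0.0388) and the young list (0.00832) lower with the share of the genome entry as a covariate, both lower without the libraries of letter B (0.00848), and the copper list higher with microRNAs fitted alone (0.0194). In the main fit with an estimated correlation, camera gave adjusted p = 0.7996 for each of these lists. Named after their values were seen, miR5634 (-1.11 ± 0.30, adjusted p = 0.00766, 5 of 6 times), miR852 (-0.70 ± 0.25, adjusted p = 0.0431) and miR5654-3p (-0.44 ± 0.15, adjusted p = 0.0327) were lower under long day.

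Over all features, 1388 passed, 769 higher and 619 lower. With totals that include the genome entry, the median log2 fold change shifted by 0.18 over all features and by 0.17 over microRNAs, and the counts became 1071 higher and 260 lower, with 5 microRNAs higher and 1 lower. The microRNA split was 10 higher and 7 lower with microRNAs alone (median shift 0.16), 2 and 14 without TMM factors, 3 and 17 with DESeq2, and 3 and 23 with the share of the genome entry as a covariate. The microRNA count also rested on single libraries. It was 18 without long day ZT 24 B and 7 without long day ZT 24 A, ZT 8 C or ZT 16 A. It was 6 without long day ZT 24 C, ZT 4 C, ZT 16 B or ZT 20 C or equinox day ZT 24 A, ZT 8 B or ZT 20 C, and 5 without equinox day ZT 16 C. The microRNAs miR5634, miR398a-3p, miR159b-5p and the miR166-3p feature were the 4 of 11 that passed without any 1 of the 54 libraries.

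Short day against equinox day asked what 4 fewer hours of light changed. Under short day, miR391-3p was higher at 46.2 ± 14.95 against 22.2 ± 10.5 CPM, and miR173-5p at 180.0 ± 80.7 against 115 ± 88.4 CPM. Under short day miR169f-3p was lower at 54.8 ± 24.2 against 101 ± 46.9 CPM, and the phosphate microRNA miR399b/c-3p at 18.02 ± 4.82 against 29.6 ± 8.17 CPM. The flowering-related miR172a/b-3p was higher, at 10.6 ± 5.06 against 6.80 ± 7.71 CPM. Of 149 microRNAs, 28 passed edgeR's quasi-likelihood test, 13 higher and 15 lower (20 adjusted over the microRNAs alone), with a median log2 fold change of 0.03 over all microRNAs.

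Of the miR172 list, 2 of 3 members were higher and 0 lower, also adjusted over the list alone, with a list median of 0.92. They were miR172c/d-3p (log2 fold change 1.30 ± 0.48, adjusted p = 0.0344, 1.78 ± 1.70 against 1.02 ± 0.976 CPM, higher at 3 of 6 times) and miR172a/b-3p (0.92 ± 0.31, adjusted p = 0.0203, 4 of 6 times, not past the threshold without short day ZT 20 A). Fry gave adjusted p = 0.0534 for this list. Of the tasiRNA and phasiRNA triggers, 3 of 12 were higher and 1 lower, also adjusted over the list alone. They were miR400 (1.04 ± 0.34, adjusted p = 0.0159), miR173-5p (0.71 ± 0.20, adjusted p = 0.00630, 4 of 6 times) and miR161.2 (0.65 ± 0.23, adjusted p = 0.0240, 4 of 6 times). The lower one was miR390b-3p (-0.52 ± 0.18, adjusted p = 0.0206, 5 of 6 times). Of the miR169 to miR171 list, 2 of 7 were higher and 1 lower, also adjusted over the list alone. They were miR171b-5p (0.70 ± 0.20, adjusted p = 0.00523) and miR171a-3p (0.65 ± 0.19, adjusted p = 0.00748), each higher at 5 of 6 times. Against these stood miR169f-3p (-0.82 ± 0.16, adjusted p = 0.000107, lower at 5 of 6 times). Of the auxin list, 1 of 14 was higher and 1 lower, also adjusted over the list alone. They were miR167a-5p/b (0.60 ± 0.20, adjusted p = 0.0174) and miR390b-3p.

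Of the meristem list, 1 of 14 was higher and 2 lower (1 and 1 adjusted over the list alone). They were miR394 (log2 fold change 0.59 ± 0.20, adjusted p = 0.0203), miR165a-5p (-0.46 ± 0.13, adjusted p = 0.00706) and miR166a/b-5p (-0.36 ± 0.14, adjusted p = 0.0486). Of the feedback list, 0 of 7 were higher and 2 lower (0 and 3 adjusted over the list alone). They were miR168b-3p, from the family that targets AGO1 (-0.43 ± 0.16, adjusted p = 0.0313), and miR162-3p at 7771 ± 3117 against 10089 ± 3348 CPM (-0.37 ± 0.15, adjusted p = 0.0474), each lower at 4 of 6 times. Of the phosphate list, 0 of 2 were higher and 1 lower, also adjusted over the list alone. It was miR399b/c-3p (-0.71 ± 0.16, adjusted p = 0.000737, 6 of 6 times). Of the 2 sulfate features, 1 was lower (both adjusted over the list alone). It was miR395b/c/f at 82.1 ± 35.1 against 129.7 ± 69.7 CPM (-0.57 ± 0.17, adjusted p = 0.0102, 5 of 6 times). Of the young list, 1 of 34 was higher and 1 lower (0 adjusted over the list alone). They were miR822-5p (0.48 ± 0.19, adjusted p = 0.0410) and miR843 (-0.63 ± 0.19, adjusted p = 0.00917).

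No member of the miR156 and miR157, miR159 and miR319 or copper lists passed edgeR's test, also adjusted over the list alone. Their log2 fold changes were 0.15 ± 0.15 for miR156a-f-5p (adjusted p = 0.462), 0.11 ± 0.15 for miR157a/b-3p (0.628), 0.01 ± 0.16 for miR159a (0.964), -0.24 for miR398b/c-3p (0.367) and -0.31 ± 0.19 for miR408-3p (0.208). Camera gave adjusted p = 0.618 for every list, and 0.098 or more in each of the other fits. Named after their values were seen, miR391-3p (1.07 ± 0.17, adjusted p = 4.90e-06, 5 of 6 times) and miR5634 (1.00 ± 0.26, adjusted p = 0.00271, 6 of 6 times) were higher under short day. Over all features 2910 passed, 1527 higher and 1383 lower. The microRNA split was 21 higher and 12 lower with DESeq2 size factors, 18 and 7 with totals that include the genome entry, 19 and 11 with the 10 most abundant features left out, and 13 and 25 with the share of the genome entry as a covariate. With the 5 short-day libraries that lay apart left out, 1923 features and 20 microRNAs passed, and 15 of the 28 microRNAs were kept. Without any 1 library, 16 of the 28 still passed, while miR390b-3p was lost in 6 of 54 fits, miR172c/d-3p in 7, miR822-5p and miR168b-3p in 17, miR162-3p in 34 and miR166a/b-5p in 37.

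The tests across the day asked which small RNAs varied with the hour within each photoperiod. In long day, miR158a-5p went from 4165 ± 1029 CPM at ZT 16, the end of light, to 993 ± 239.9 at ZT 24, and miR779.2 from 42.2 ± 0.732 at ZT 16 to 8.07 ± 2.68 at ZT 24. In equinox day, miR169f-3p stood at 163 ± 33.6 CPM at ZT 12, the end of light, and 44.7 ± 12.2 at ZT 24, and miR165a-5p at 655 ± 88.7 at ZT 12 and 232 ± 65.0 at ZT 20. In short day, miR779.2 was highest at ZT 4 with 29.6 ± 14.7 CPM and lowest at ZT 12 with 6.65 ± 1.41. There miR160c-3p, of a family that targets ARF transcripts, was highest at ZT 24 with 164 ± 46.7 and lowest at ZT 8 with 48.3 ± 6.85.

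In long day 1180 features and 7 microRNAs varied with time by edgeR's quasi-likelihood test (3 adjusted over the microRNAs alone). They were miR158a-5p (adjusted p = 0.000340), miR779.2 (adjusted p = 0.00112) and miR157a-c-5p, which like miR156 targets SPL transcripts (adjusted p = 0.0151, 459.6 ± 61.5 CPM at ZT 4 and 149 ± 14.5 at ZT 20). Further ones were miR165a-5p (adjusted p = 0.0214, 651 ± 109 at ZT 16 and 262 ± 32.1 at ZT 20), miR5595a/miR5995b (adjusted p = 0.0327), miR5642a/b (adjusted p = 0.0392) and miR159b-5p (adjusted p = 0.0454). Among them, miR779.2, miR5595a/miR5995b and miR5642a/b are in no list and were named after their values were seen. In equinox day 461 features and 6 microRNAs varied (5 adjusted over the microRNAs alone). They were miR779.2 (adjusted p = 0.00909, 33.6 ± 9.18 CPM at ZT 12 and 10.3 ± 7.44 at ZT 24), miR169f-3p (adjusted p = 0.0127), miR165a-5p (adjusted p = 0.0142), miR395b/c/f (adjusted p = 0.0203), miR167d (adjusted p = 0.0294) and miR173-5p (adjusted p = 0.0498, 188 ± 94.2 at ZT 8 and 61.1 ± 23.8 at ZT 12). In short day 354 features and 2 microRNAs varied, miR779.2 (adjusted p = 0.00101) and miR160c-3p (adjusted p = 0.0464), with 1 adjusted over the microRNAs alone. Other groupings of the short-day libraries into 6 times gave up to 1079 features. In equinox day and short day, other groupings gave up to 28 and 8 microRNAs, so chance cannot be excluded for the microRNA counts there. The varying features peaked most often at ZT 20 (393) and ZT 16 (335) in long day, at ZT 4 (215) and ZT 12 (104) in equinox day, and at ZT 4 (122) and ZT 8 (116) in short day. At equinox day ZT 4, library C differed from A and B more than replicates did elsewhere (chi-square per degree of freedom 171 and 212).

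By list, the members that varied in long day were 1 of the miR156 and miR157 list (2 adjusted over the list alone), 1 of the miR159 and miR319, meristem and young lists (1 each) and 0 of the phosphate list (1). In equinox day they were 1 of the auxin list (3 adjusted over the list alone), 1 of the meristem list (2), 1 of the miR169 to miR171, sulfate and trigger lists (1 each) and 0 of the miR172, miR159 and miR319 and feedback lists (1 each). In short day they were 1 of the auxin list (2 adjusted over the list alone) and 0 of the copper list (3). All other lists had 0 members past edgeR's test, with 0 adjusted over the list alone. Two-sided Fisher's exact tests of the lists against all other features gave 0 of 48 list results past the threshold, 0 with an unadjusted p under 0.05 and a smallest unadjusted p of 0.0781. As a class, 7 of 149 microRNAs varied in long day against 13.5% of the other features (two-sided Fisher's exact p = 0.000884). By the same Fisher's exact test it was 6 of 149 against 5.22% in equinox day (p = 0.708) and 2 of 149 against 4.04% in short day (p = 0.134). In long day it was 4 of 149 against 4.32% with the share of the genome entry as a covariate (two-sided Fisher's exact p = 0.418), and with microRNAs fitted alone 31 varied.

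Single libraries moved these counts. In long day 715 features passed without ZT 16 A and 758 without ZT 16 B. The microRNAs numbered 3 without ZT 16 A or B and 4 without ZT 8 C or ZT 20 B, while miR157a-c-5p, miR779.2 and miR158a-5p passed without any 1 library. In the same test miR165a-5p was lost without ZT 16 A, B or C, miR5595a/miR5995b in 6 of 54 fits, and miR159b-5p and miR5642a/b in 17. In equinox day 305 features passed without ZT 4 C, 292 without ZT 8 B and 307 without ZT 16 C. There miR395b/c/f was lost without ZT 16 C, miR169f-3p without ZT 24 B, miR779.2 without ZT 16 A, miR165a-5p without ZT 12 A, ZT 12 C or ZT 16 A, miR167d in 5 fits and miR173-5p in 34. Of the short-day microRNAs, miR779.2 passed without any 1 library and miR160c-3p was lost in 36 of the 54 fits. With the share of the genome entry as a covariate, 381 features varied in long day, 570 in equinox day and 382 in short day.

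The interaction test asked whether the course over the day itself differed between photoperiods. The peak of miR779.2 fell at ZT 16 in long day, ZT 12 in equinox day and ZT 4 in short day, and 4 h after lights went off it stood at 14.7 ± 3.4, 11.2 ± 2.66 and 6.65 ± 1.41 CPM. For miR169f-3p the level was highest at ZT 20 in long day (172 ± 3.66 CPM), at ZT 12 in equinox day (163 ± 33.6) and at ZT 4 in short day (84.2 ± 34.9). For miR173-5p it was highest at ZT 4 in long day (141 ± 43.4), ZT 8 in equinox day (188 ± 94.2) and ZT 24 in short day (298 ± 54.8).

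By edgeR's quasi-likelihood test, 525 features and 5 microRNAs had courses that differed between photoperiods (5 adjusted over the microRNAs alone). They were miR779.2 (adjusted p = 0.000312), miR158a-5p (adjusted p = 0.00511), miR169f-3p (adjusted p = 0.00923), miR165a-5p (adjusted p = 0.0146) and miR173-5p (adjusted p = 0.0308). They included 1 member each of the meristem, trigger and young lists (1 each adjusted over the list alone) and 1 of the miR169 to miR171 list (2), with 0 members of the miR172, auxin and feedback lists (1 each adjusted over the list alone) and of all other lists (0). The count of features was 340 without equinox day ZT 8 B and 861 without short day ZT 4 A. The count of microRNAs was 11 without short day ZT 4 A, 10 without equinox day ZT 8 C, 9 without equinox day ZT 4 C or short day ZT 4 B, and 8 without equinox day ZT 24 A or ZT 20 B or short day ZT 4 C. The interaction of miR173-5p was lost without long day ZT 4 B or C, equinox day ZT 8 A or B, or short day ZT 24 B.

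**Figure D2:**
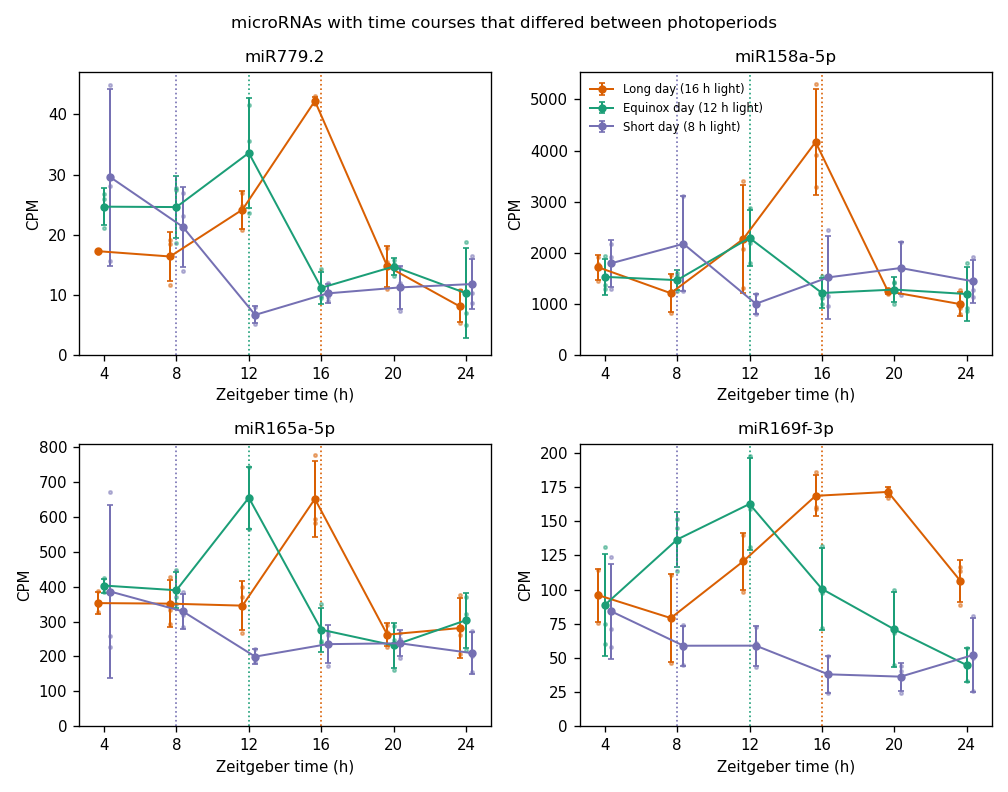
Mean CPM ± SD of 3 libraries (points are single libraries) against Zeitgeber time in hours for miR779.2, miR158a-5p, miR165a-5p and miR169f-3p in long day, equinox day and short day; dotted lines mark the end of light, and the photoperiods are drawn side by side at each time. In long day miR779.2 stood at 42.2 at ZT 16 and 14.7 at ZT 20, in equinox day at 33.6 at ZT 12 and 11.2 at ZT 16.

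Single times asked at which hours long day and short day stood apart. The time ZT 16 is the end of light in long day and falls in the dark of short day. There miR169f-3p stood at 169 ± 14.9 against 38.0 ± 13.7 CPM, miR165a-5p at 651 ± 109 against 235 ± 53.9 CPM and miR158a-5p at 4165 ± 1029 against 1517 ± 810.5 CPM. At ZT 20, in the dark under both, miR169f-3p stood at 172 ± 3.66 against 36.3 ± 10.3 CPM. At ZT 12 miR779.2 stood at 24.2 ± 3.15 against 6.65 ± 1.41 CPM.

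By edgeR's quasi-likelihood test, 347 features passed at ZT 16, 298 higher and 49 lower under long day, with 6 microRNAs, 5 higher and 1 lower (10 adjusted over the microRNAs alone). They were miR169f-3p (log2 fold change 2.15 ± 0.40, adjusted p = 0.000290), miR779.2 (2.04 ± 0.41, adjusted p = 0.000763), miR165a-5p (1.47 ± 0.33, adjusted p = 0.00324), miR158a-5p (1.46 ± 0.37, adjusted p = 0.0107), miR829-5p (1.24 ± 0.34, adjusted p = 0.0227) and miR5634 (-3.06 ± 0.71, adjusted p = 0.00489). At ZT 12, 308 passed (217 higher, 91 lower), with miR779.2 (1.86 ± 0.41, adjusted p = 0.00470), miR5634 (-2.37 ± 0.63, adjusted p = 0.0242) and miR391-3p (-1.40 ± 0.41, adjusted p = 0.0458) among the microRNAs. At ZT 20, 109 passed (68 higher, 41 lower), with miR169f-3p as the 1 microRNA (2.24 ± 0.40, adjusted p = 0.00128). Of these, miR779.2, miR829-5p, miR5634 and miR391-3p are in no list and were named after their values were seen. At ZT 8, 121 passed (95 higher, 26 lower), at ZT 24, 56 (43 higher, 13 lower), and at ZT 4, 11 (1 higher, 10 lower). No microRNA passed edgeR's test at ZT 4, ZT 8 or ZT 24, where 5, 8 and 36 had an unadjusted p under 0.05 and DESeq2 called 0, 1 and 18.

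With 3 libraries against 3, single libraries moved these counts. Leaving out long day A, B or C gave 158, 173 and 191 features at ZT 12, 30, 50 and 60 at ZT 20, and 6, 29 and 92 at ZT 24. Leaving out short day A or B gave 203 and 216 at ZT 16, B or C gave 162 and 152 at ZT 12 and 12 and 4 at ZT 24, and A, B or C gave 24, 39 and 43 at ZT 20 and 39, 58 and 63 at ZT 8. At ZT 8 the count was 67 without long day A, and at ZT 4 it was 2 and 4 without long day B or C and 162 and 4 without short day A or C. At ZT 16, miR829-5p was lost without long day A or C or short day A or B, miR158a-5p without long day A or short day A or B, and miR165a-5p without short day B. At ZT 12, miR5634 was lost when any of the ZT 12 libraries of long day or short day was left out, and miR391-3p was lost in 23 of the 54 fits. With the 5 short-day libraries that lay apart left out, 183 features passed at ZT 12, 43 at ZT 20 and 6 at ZT 24.

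The share of microRNAs among the counts outside the genome entry asked whether the class as a whole differed between photoperiods. It was 9.43 ± 1.33% in long day, 11.0 ± 2.23% in equinox day and 10.0 ± 1.88% in short day (n = 18 each). Long day differed from equinox day by -1.58 percentage points and was higher at 1 of 6 times (two-sided permutation p = 0.00824, adjusted over 6 tests 0.0494). The difference between medians did not pass (adjusted permutation p = 0.219), and neither did long day against short day (0.300) or short day against equinox day (0.292). The share of the genome entry was 84.9 ± 3.26% in long day, 86.9 ± 2.41% in equinox day and 86.1 ± 3.83% in short day, with an adjusted permutation p of 0.125 for long day against equinox day. Within long day it ranged from 80.8 ± 1.6% at ZT 16 to 89.1 ± 0.900% at ZT 20 (permutation p = 0.00433, adjusted 0.0260), while its variation with time had adjusted p = 0.632 in equinox day and in short day. The microRNA share by time gave adjusted permutation p = 0.355 in long day, 0.227 in equinox day and 0.227 in short day.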

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

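Of the tests in this part, the count of varying features with the share of the genome entry as a covariate, the part of the end-of-light change that the share gives in equinox day, the calls of the end-of-light microRNAs with the share as a covariate and the microRNA counts of the random splits were chosen after the result was seen. The courses of 5 microRNAs over the day differed between photoperiods in the interaction test of edgeR's quasi-likelihood fit: miR779.2 (adjusted p = 0.000312), miR158a-5p (0.00511), miR169f-3p (0.00923), miR165a-5p (0.0146) and miR173-5p (0.0308). The genome entry, which the tests of features left out, held 86.1% of all counts.

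The first pattern concerns miR779.2, miR158a-5p and miR165a-5p, which were higher at the end of light than 4 h later. Their log2 changes were 1.59 ± 0.23, 1.26 ± 0.21 and 1.09 ± 0.19 as means over the 3 photoperiods, the only form tested. The change was positive in each photoperiod, from 0.72 for miR165a-5p in short day to 1.74 for miR158a-5p in long day, but was not tested in each alone. In short day the peak of miR779.2 fell at ZT 4, before the end of light. With the share of the genome entry as a covariate all 3 stayed past the threshold (log2 changes of 1.29, 0.84 and 0.79, highest adjusted p = 0.00715), which argues against the share as the whole cause. Of their median change 66.7% was left, and for the rest the share and the end of light cannot be told apart, because the share itself moved at the end of light in long day. In equinox day the change in the share gave 5.86% of the median log2 change of 1.24, which argues against the share there. As a candidate biological explanation, the end of the light period may be a general time mark for microRNAs. Between the end of light and 4 h later 9 passed, against 5 in the fixed 4 h step with the most, ZT 24 to ZT 4. That step spans lights on in every photoperiod, so it is itself set on a change of light. Each of the other fixed steps gave 0 microRNAs. The 9 include the 3 microRNAs of this pattern, so the count partly restates it. With the share as a covariate the order turned, with 7 at the end of light and 10 from ZT 24 to ZT 4. The general time mark thus stays a hypothesis.

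The second pattern is that more features varied with time in long day than elsewhere, 1180 against 461 in equinox day and 354 in short day, a ratio of 2.56 to the larger of these. With the share of the genome entry as a covariate the counts were 381, 570 and 382 and the ratio 0.668. The share itself differed with time in long day (80.8 ± 1.6% at ZT 16 and 89.1 ± 0.900% at ZT 20, adjusted permutation p = 0.0260), so the share and the time of day cannot be told apart as the source of the excess, and whether the share moved with sample handling or with the seedlings was not tested. A single library stays open as well: the lowest long-day count without 1 library was 715 (without ZT 16 A, beside 439 in equinox day in that fit), above the limit of 691.5, which is 1.5 times the equinox-day count, by less than the SD of 128.5 over such counts. Without the libraries of letter B the order turned, with 23 features in long day, 98 in equinox day and 127 in short day.

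Libraries were also regrouped at random into groups of the same sizes, 100 splits per test with the real one included. For the counts of all features, chance can be excluded for long day against short day (2229 features, highest other split 867, with 1 split reaching the real count, the real one), short day against equinox day (2910, highest other 926, 1 split), time in long day (1180, highest other 170, 1 split), time in equinox day (461, highest other 305, 1 split) and the interaction (525, highest other 396, 1 split). For long day against equinox day (1388), 2 of the 100 splits reached the real count, a share under 0.05. The highest other gave 1501, more than the real count, so chance is less firmly excluded there. For time in short day (354) chance cannot be excluded, since 10 splits gave as many, and the highest other split gave 1079, several times the real count, which points to a structure of these libraries that no test here identified. For the single times the 10 possible splits are too few for a share under 0.05. The real counts and the highest of the other splits were 11 and 18 at ZT 4, 121 and 0 at ZT 8, 308 and 196 at ZT 12, 347 and 0 at ZT 16, 109 and 0 at ZT 20, and 56 and 29 at ZT 24.

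For the counts of microRNAs in the same splits, chance can be excluded for long day against short day (43 microRNAs, highest other split 2, with 1 split reaching the real count, the real one), long day against equinox day (11, highest other 2, 1 split) and time in long day (7, highest other 1, 1 split). For the interaction (5, highest other 0, 1 split) the splits cannot decide, because they also broke up the differences between photoperiods. For short day against equinox day (28), 2 splits reached the real count, a share under 0.05. The highest other gave 39, more than the real count, so chance is less firmly excluded there. For time in equinox day (6) and time in short day (2) chance cannot be excluded, since 6 and 9 splits gave as many microRNAs. The highest other splits there gave 28 and 8, several times the real counts, which points to a structure of these libraries that no test here identified. The single times with microRNAs past the threshold have too few splits, with real counts of 3 at ZT 12, 6 at ZT 16 and 1 at ZT 20 and 0 as the highest other at each.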

How the results depend on the processing

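Of the tests in this part, those with the share of the genome entry as a covariate, with totals that include the genome entry, with microRNAs alone (for the counts), with sets of 3 or 5 libraries left out and with 1 library left out at single times were chosen after the data were seen. So were the list tests under alternatives, except families summed, the replicate block and microRNAs alone for the photoperiods. For the microRNAs that passed between photoperiods or at a single time, 0 of 4968 log2 fold changes with 1 library left out and 0 of 1484 under the other settings turned direction. Since these microRNAs were picked for passing, turns were unlikely by construction, and many of the left-out libraries were not among those compared. Of the 43 microRNAs between long day and short day, 42 were kept with DESeq2, 41 with the share as a covariate, 28 with totals that include the genome entry and 17 with no filter. Counts named below are features past the threshold, or microRNAs where so named; all others stayed within 1.5 times their value, and the cause of the changes was not tested except where fewer libraries or a stricter threshold lower a count by construction.

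At an adjusted p under 0.01 the counts were 997 for long day against short day (19 microRNAs), 768 for long day against equinox day (4), 1622 for short day against equinox day (9), 397 for time in long day (2), 193 for time in equinox day (with 1 microRNA), 1 microRNA for time in short day, and 160 for the interaction (3). With an absolute log2 change of at least 1 the photoperiod counts were 1181, 613 and 1472 (5, 1 and 3 microRNAs). With no filter (223651 features) the microRNAs were 17, 0 and 8 for the photoperiods, 2, 3 and 1 for time in long, equinox and short day, with 589 features for time in long day, and single times gave 71 features at ZT 4, 59 at ZT 8, 83 at ZT 12, 171 at ZT 16 and 100 at ZT 24. The 0 microRNAs of edgeR for long day against equinox day stand beside 28 with an unadjusted p under 0.05 and 20 by DESeq2 in the filtered table.

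With DESeq2 the microRNAs were 20 for long day against equinox day, 17, 18 and 6 for time in long, equinox and short day and 22 for the interaction, and features were 889 for time in equinox day, 1433 for the interaction, 39 at ZT 4 and 241 at ZT 24. With DESeq2 size factors in edgeR the microRNAs were 17 for long day against equinox day, 11 for time in long day and 11 for the interaction. Without TMM factors the microRNAs were 11, 36 and 6 for time in long, equinox and short day and 38 for the interaction, which had 1170 features, and 4 lists passed in the time tests, where 0 did otherwise. With the 10 most abundant features left out, time in short day had 1 microRNA. With totals that include the genome entry the microRNAs were 28 for long day against short day, 6 for long day against equinox day and 1 for time in short day. With microRNAs alone they were 67, 17 and 63 for the photoperiods, 31, 27 and 24 for time and 37 for the interaction. At the single times the microRNAs were 1, 5, 12 and 18 with DESeq2 at ZT 8, 12, 16 and 24, 10 and 3 with DESeq2 size factors at ZT 16 and 24, 1 with no filter at ZT 16 and 2 with the share as a covariate at ZT 24. With microRNAs alone they were 1, 2, 45, 29, 3 and 29 from ZT 4 to ZT 24. At ZT 12 edgeR called 0 with no filter and 0 with only the 6 libraries, beside 35 with an unadjusted p under 0.05 in the full fit.

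With only the libraries of the photoperiods compared, the microRNAs were 21 for long day against equinox day and 15, 2 and 0 for time in long, equinox and short day (edgeR, where 19 short-day microRNAs had an unadjusted p under 0.05 in the full fit and DESeq2 called 6), and time in short day had 155 features; with only the 6 libraries of a time, 3 features passed at ZT 4, 41 at ZT 12 and 3 at ZT 24. With a cosine of 24 h, time in long day had 235 features and 3 microRNAs, and time in short day 1 microRNA. With the share of the genome entry as a covariate the microRNAs were 26 for long day against equinox day and 4, 10 and 4 for time in long, equinox and short day, with 381 features for time in long day and 19 at ZT 4. With the 3 shallowest libraries left out (under 1.6 M counts outside the genome entry), long day against short day had 1362 features, the interaction 9 microRNAs and ZT 24 had 4 features. With the 5 short-day libraries that lay apart left out, the counts were 994 for long day against short day, 1923 for short day against equinox day, 183 at ZT 12, 43 at ZT 20 and 6 at ZT 24, with 1 microRNA for time in short day and 8 for the interaction.

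Of the camera tests of the photoperiod lists, 1 passed: miR156 and miR157 between long day and short day. The number was 0 with families summed, where miR156 and miR157 make 2 families and could not be tested, 0 with the replicate block (miR156 and miR157 adjusted p = 0.0513), 0 with totals that include the genome entry, 4 with DESeq2 size factors, 4 with the 10 most abundant features left out, 4 with the filter of 1 CPM in 27 libraries (10324 features in place of 8869), 6 with the share as a covariate, 4 without the 3 shallowest libraries and 5 without the 5 short-day libraries. The added calls between long day and short day were the auxin, trigger and young lists in each of these last 6 settings, and the meristem list (0.0482) in the last; the other 2 with the covariate were miR156 and miR157 and young between long day and equinox day. The 1 call with microRNAs alone was another, copper between long day and equinox day; over all fits with the preset correlation the adjusted p of miR156 and miR157 between long day and short day ran from 9.95e-05 to 0.238, and with an estimated correlation it was 0.812. In the main fit, camera with an estimated correlation also gave adjusted p = 0.812 for the auxin, trigger and young lists between long day and short day. With the replicate block, long day against short day had 2125 features and 39 microRNAs. The 1 microRNA share that passed became 0 when medians were compared.

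Leaving out each library or each replicate letter gave 867 to 2523 features for long day against short day (15 to 47 microRNAs), 591 to 1583 for long day against equinox day (0 to 18), 1234 to 3340 for short day against equinox day (4 to 37), 23 to 1328 for time in long day (0 to 9), 79 to 603 in equinox day (0 to 9), 127 to 396 in short day (0 to 3) and 12 to 861 for the interaction (0 to 11). Single times gave 2 to 162 at ZT 4, 3 to 141 at ZT 8, 4 to 382 at ZT 12, 96 to 408 at ZT 16, 0 to 125 at ZT 20 and 0 to 92 at ZT 24, with 0 to 1, 0 to 0, 0 to 4, 2 to 9, 0 to 1 and 0 to 1 microRNAs. Photoperiod lists that passed camera numbered 0 to 7, and lists in the time tests 0 to 0. Leaving out a letter leaves 2 libraries per group. On simulated features with this design, 4 of 50 changes of 1.5-fold were found between long day and short day and 0 of 50 of 2-fold for time in equinox day, so most changes of these sizes were missed; other depths were not simulated.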

Other observations

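Of the tests in this part, the shift of the miR390b arm ratio, the test of a change in MIR390a alone and the arm ratios of pairs with no shared feature were chosen after the result was seen. Aligned on the end of light (ZT 16 in long day, ZT 12 in equinox day, ZT 8 in short day), 730 features differed from their level 4 h later over the 3 photoperiods by edgeR's quasi-likelihood test, 465 higher and 265 lower at the end of light. There were 256 with the share of the genome entry as a covariate, while the step from ZT 24 to ZT 4 went from 402 to 464. Among the 730 were 9 microRNAs, 7 higher and 2 lower. Beside miR779.2, miR158a-5p and miR165a-5p, the higher ones were miR168a-3p (log2 fold change 1.01 ± 0.19) and miR168b-3p (0.80), from the family that targets AGO1, miR825 (0.83) and miR829-5p (0.78). The lower ones were miR5634 (-1.57 ± 0.40) and miR5996 (-1.15), which the annotation places in an exon of AT4G13560. Of these, miR168b-3p (0.48, adjusted p = 0.272), miR825 (0.52, adjusted p = 0.191), miR829-5p (0.47, adjusted p = 0.219) and miR5996 (-1.29, adjusted p = 0.0796) did not pass with the share as a covariate. The opposite arms of the leading precursors did not pass: miR158a-3p had a log2 fold change of 0.26 (adjusted p = 0.409) and miR165a-3p/b, a feature that pools MIR165a and MIR165b, of -0.06 (adjusted p = 0.904).

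One hypothesis was that passenger strands, as the short-lived arm of a precursor, are further up at the end of light. The precursors of miR158a and miR165a, in which the pattern was seen, were left out. Over the other 41 precursors with both arms tested, some of which share a pooled feature, the less abundant arm was further up in 22. The mean difference was 0.09 on the log2 scale (SD 0.54). The two-sided permutation p, from random flips of the signs of the differences, was 0.291. The test gave no sign of such a rule.

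The arms of miR390b had been called in opposite directions between long day and short day, so their ratio was bound to differ, and its test is no separate evidence. The log2 ratio of the 5p feature to miR390b-3p was 1.17 ± 0.366 in long day and 2.59 ± 0.753 in short day (n = 18 each), lower in long day at 6 of 6 times. Its permutation p adjusted over 129 tests was 0.00129, from the smallest p the draws can give. Arm ratios of 20 of 43 precursors shifted between long day and short day, 7 of them toward the 5p arm, 12 between long day and equinox day and 11 between short day and equinox day. These ratios are not independent, since 21 of the 43 share a pooled feature with another, miR156a-f-5p standing in 5 of them. Of the 22 that share none, 11, 6 and 6 shifted in these comparisons. With the share of the genome entry regressed out, 20, 9 and 11 of all shifted ratios stayed past the threshold, which argues against that share as the cause between long day and short day. Photoperiod may act on which arm is kept or read, but the 5p feature pools MIR390a and MIR390b. A change in MIR390a alone would leave miR390b-3p near its level, and the log2 fold change of that arm was 0.81 ± 0.18. That arm was taken up because it had been called, so this value restates the call and is no separate evidence against MIR390a alone. The ratio of the 5p feature to miR390a-3p was also lower in long day, by 0.39 on the log2 scale (adjusted permutation p = 0.0182, lower at 4 of 6 times), and from which precursor the 5p counts were lost stays open.

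With the names of each family summed, the miR156 family had a log2 fold change of -0.58 ± 0.16 between long day and short day (adjusted p = 0.00619 over 86 families, edgeR) and the miR157 family of -0.34 ± 0.16 (adjusted p = 0.124). The replicate letters did not pair the libraries: the mean correlation of same-letter residuals was -0.0098, and 19 of 54 libraries were closest to a library of their own letter.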
